A study of Mus musculus with 2 samples.

How the data were processed

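RNA sequencing of mouse villi of both genotypes was analysed from a single table for the whole series. Per the labels, RNA was purified from small-intestinal villi with a column kit, libraries were made with a TruSeq RNA v2 kit, and 1 library was sequenced per genotype. Per the submitters' processing notes, TopHat, DESeq and the mm9 build were used, with no versions. The counting tool, the treatment of duplicate reads and the strand setting are not given in the sources used here.

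The deposited signal columns are normalised read counts (DESeq base means, per the file headers), 1 row for each of 22040 RefSeq transcripts. Every value was a whole multiple of the smallest value of its column, 1.0533 in the control and 0.9494 in the dKO-labelled library, in 100% of rows within 0.001 of a step, and no value was 0. The smallest value covered 42.6% of control rows and 34.9% of dKO rows, and the rows at 2, 3 and 4 steps numbered 2199, 1102 and 664 in the control. The values are read here as counts to which 1 read had been added before normalisation, an inference from the values that no label states. Reads were recovered as steps minus 1, which gave 775827 and 1058196 reads. The deposited fold (ratio) and log2 columns equal the quotient of the 2 signal columns and its log2, and the deposited p-value column, by the authors with DESeq, is unadjusted. Used columns cover all value columns of the table.

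Symbols with several rows (1171) were represented by the row with the highest mean, which left 20722 symbols. Of the identifiers, 21716 (98.5%) matched a RefSeq table of assembly GRCm38.p6. It was used for names alone, and it resolved 32 of 33 symbols that a spreadsheet had turned into dates. Transcript lengths came from GENCODE M21. Both differ from mm9, so no coordinates are printed.

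The main measure was log2((dKO + 1)/(control + 1)) of the deposited normalised counts. A gene was measured at a mean of at least 20 and called higher or lower by size at 2-fold, without a test. Printed folds are ratios of recovered reads divided by the ratio of the deposited size factors (1.11), with 95% Clopper-Pearson intervals. A count of 0 was set to a floor of 3 reads. Each gene list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, if at least 3 members were measured. A percentile describes these libraries. For Hox, developmental and germline genes, genes with at most 3 normalised reads in a library and at least 10 in the other were counted. A transcript with 2 control reads has a normalised count above 3 and is outside that rule. Random lists for these counts were drawn from all genes with at most 3 in the control. They were matched on control reads alone, and that pool includes genes with no read in either library.

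The lists, the tests and the rule for named genes were fixed before the data were examined. Named genes were the 12 highest and 12 lowest ratios at a mean of at least 50, the 6 highest and 6 lowest at a mean of at least 1000, up to 4 members of each list with the largest absolute log2 ratio, the targeted genes, and up to 6 near-silent members per direction. Predicted and unnamed genes were passed over, which concerned 1 gene. Some genes that the rule names are not reported here.

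Alternatives were total-count, upper-quartile and TMM scaling, a pseudocount of 5, other filters, an interval-based size rule and unmatched random lists. Added after seeing the data were a median set to 0, thinning of the deeper library, random lists matched also on transcript length (10 expression and 5 length bins), removal of the added read, summing of rows, the authors' unadjusted p-values and an exact binomial test on the reads. The binomial test compares the libraries, not the conditions. TMM used edgeR 4.0.16 in R 4.3.3, and all else Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

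The functions were tested on simulated data, with Poisson reads for the real genes at the real depths and 200 changed genes. Over 5983 measured genes of the simulated comparison, the 2-fold rule found 100% of 50 genes made 4-fold higher and 95.3% of 43 made 4-fold lower. At exactly 2-fold it found 44.0% of those higher and 36.6% of those lower, and it called 11 of 5799 unchanged genes. The simulation holds counting error and no difference between animals.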

Results

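Messenger RNA was sequenced from purified villi of the mouse small intestine, the fingers of the mucosa that carry the differentiated epithelium. Ring1 (also called Ring1a) and Rnf2 (Ring1b) encode the E3 ubiquitin ligases of Polycomb repressive complex 1 (PRC1), which marks histone H2A and keeps developmental genes silent. The control library came from a C57BL/6 mouse with a tamoxifen-inducible Cre recombinase and no functional Cdkn2a. The other library was labelled as the same background with a constitutive loss of Ring1 and a conditional Rnf2 allele (dKO, double knockout). Both were taken 6 days after 3 tamoxifen injections. Each genotype had 1 library, so no difference below has a replicate check, and every comparison is between these 2 libraries. The control library held 775827 recovered reads over 12658 detected RefSeq transcripts, and the dKO-labelled library 1058196 reads over 14351. Intervals are 95% exact counting intervals and cover counting error only.

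The targeted genes were examined first. Ring1 (NM_009066) had 10 reads in the control and 10 in the dKO-labelled library, a ratio of 0.901 after scaling (0.337 to 2.41). Rnf2 (NM_011277) had 59 and 82 reads, a ratio of 1.25 (0.886 to 1.78). Neither gene was lower beyond counting error. The Rnf2 log2 ratio of 0.31 became -0.20 with edgeR's TMM scaling and -0.32 with upper-quartile scaling. Counts over whole transcripts do not show which exons were deleted, so these values neither support nor exclude the label, and the library is called dKO-labelled throughout. Cdkn2a, encoding the p16 and p19 inhibitors and absent by design from both genotypes, had 0 reads in the control and 1 in the dKO-labelled library. It has 2 transcripts in the table. Other genes with 2 transcripts were as low, such as Kdm2b (0 and 1 reads) and Slc7a9 (1 and 0), though Dpp4 had 220 and 192. The low Cdkn2a count is therefore no check of the allele.

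The comparison asks which villus genes differ when PRC1 ligases are removed. The genes with the highest ratios were led by Hoxb13, a posterior homeobox gene, with 0 reads in the control and 451 in the dKO-labelled library. With the control set to a floor of 3 reads it was 135.5-fold higher, and the lower limit of the counting interval was 109.8. Maob, a mitochondrial monoamine oxidase, had 1 and 224 reads, a ratio of 202 (35.9 to 8010). Apol10a had 13 and 527 reads (36.5-fold, 21.2 to 69.1), the water channel gene Aqp1 3 and 140 (42.1-fold, 14.1 to 206), and Pck1, the key enzyme of gluconeogenesis, 6 and 195 (29.3-fold, 13.2 to 80.8). Cyp2c55, Akr1c14, Gstm3 and Tst, enzymes of detoxification and steroid or sulfur metabolism, were 60.7-, 114-, 26.0- and 22.9-fold higher, and the class I gene H2-Q10 41.1-fold. Reads of H2-Q10, Akr1c14 and Gstm3 can be shared with close paralogs, so their values are uncertain. The Y-linked genes Ddx3y and Eif2s3y completed the 12 highest.

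Lowest was Slfn4, an interferon-inducible Schlafen gene, with 390 reads in the control and 12 in the dKO-labelled library, 36.1-fold lower (20.4 to 70.4). Oas2 was 13.2-fold lower (7.67 to 24.7), the cholesterol exporter Abca1 12.8-fold (7.43 to 24.0), the acute-phase gene Saa1 11.9-fold (6.21 to 25.5), Ubd 9.34-fold (6.21 to 14.6) and the sodium-proton exchanger Slc9a3 9.14-fold (5.79 to 15.1). Adrb3, Erich2, Ly6d and Ppap2b were 14.3-, 9.54-, 7.87- and 7.56-fold lower. The nuclear RNA Malat1 had 6968 reads in the control and 1211 in the dKO-labelled library, 6.38-fold lower (6.00 to 6.79). Among genes with a mean of at least 1000, Apob (3.51-fold), Neat1 (2.65-fold), Lmo7, Fcgbp and Nt5e followed Malat1, and Eef2 (2.66-fold), Pigr (2.28-fold), Lyz1, Vil1, Eef1a1 and Myo1a had the highest ratios. Slfn4, Saa1 and Lyz1 have close paralogs and are uncertain in the same way.

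Of 6001 measured genes, 1574 were at least 2-fold higher and 251 at least 2-fold lower in the dKO-labelled library, 86.2% of them higher. This split followed the scaling. It was 972 higher and 436 lower with total counts, 664 and 652 with TMM, 528 and 818 with the upper quartile, and 680 and 642 when the median of measured genes was set to 0, the last chosen after seeing the data. The median log2 ratio of measured genes was 0.51 with the deposited size factors, and counts of gene groups relative to it are given where they differ from the main ones. In the authors' deposited table, 123 transcripts had an unadjusted DESeq p-value under 0.05, 104 of them higher and 19 lower. With 1 library per group there were no replicates from which to measure spread, so these counts show neither presence nor absence of differences. After Benjamini-Hochberg adjustment of the deposited p-values the smallest was 0.392.

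**Figure D1:**
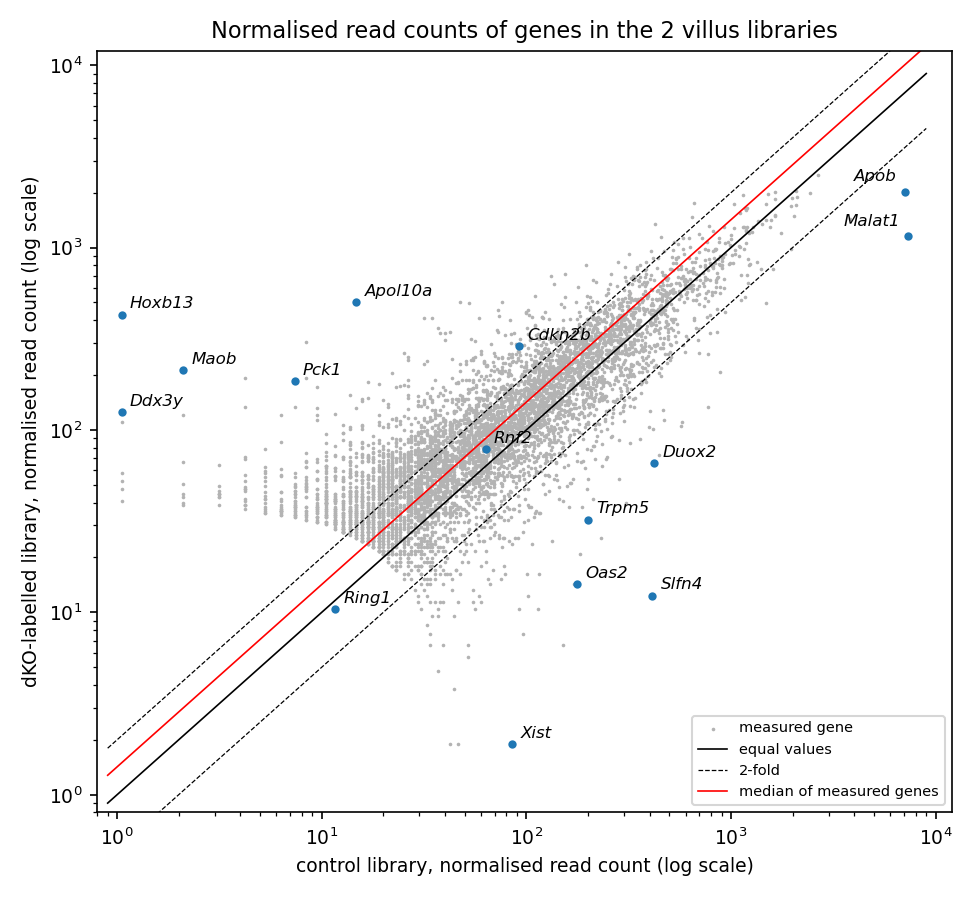
Normalised read counts of the 6001 measured genes in the control library (horizontal, log scale) and in the dKO-labelled library (vertical, log scale), each point a gene, with named genes in blue, Ring1 added below the measured range. The solid black line marks equal values, dashed lines 2-fold, and the red line the median log2 ratio of 0.51. Hoxb13 stands farthest above the line and Slfn4, Oas2 and Xist far below it.

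Hox genes, which pattern the body axis and are classical Polycomb targets, were detected more widely in the dKO-labelled library. Reads were found for 8 of 39 Hox genes in the control and for 32 in the dKO-labelled library, and 32 had more reads there while 0 had fewer. These are reads before scaling, and the dKO-labelled library was the deeper one. Over all genes 12269 symbols were detected in the control and 13925 in the dKO-labelled library, and of 148 other developmental factors 40 and 82. Of 34 with at most 3 normalised reads in the control, 7 (20.6%) had at least 10 in the dKO-labelled library, against 259 of 10473 (2.47%) among all genes at that level, and 0 of 10000 random lists reached as many. In the other direction the number was 0 of 16, against 44 of 9975 (0.441%) among all genes, too low a share for 16 genes to show a direction. With at least 20 reads required, only Hoxb13 met the rule. Next to Hoxb13, Hoxb4 had 2 and 51 reads (23.0-fold, 6.05 to 195), and Hoxb6, Hoxb7, Hoxc8, Hoxc10 and Hoxc9 had 0 reads in the control and 17, 16, 14, 13 and 11 in the dKO-labelled library. Hoxb13 made up 64.8% of the Hox reads of that library. Without it, Hox reads numbered 19 and 245, 11.6-fold higher (7.28 to 19.6).

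Among other developmental transcription factors, 8 of 125 near-silent in the control (6.40%) had at least 10 normalised reads in the dKO-labelled library, and 74 of 10000 random lists reached as many. They included Barx1 (0 and 21 reads), Sim2 (1 and 18), Otx1 (0 and 16), Evx1 and Zic2 (0 and 13 each) and Foxl2 (0 and 12). Pitx1 had 3 and 49 reads (14.7-fold, 4.75 to 73.8). The count in the other direction was 0 of 97, against 44 of 9975 (0.441%) among all genes. Of 18 near-silent germline genes 0 met the rule, and the random lists for them had a median of 0. Lists this short cannot show a direction or a contrast by such zeros. Markers of stromal cells were also higher in this library, as described below: 99 reads in the control and 591 in the dKO-labelled library over 21 fibroblast and smooth muscle genes, 5.38-fold (4.34 to 6.73).

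**Figure D2:**
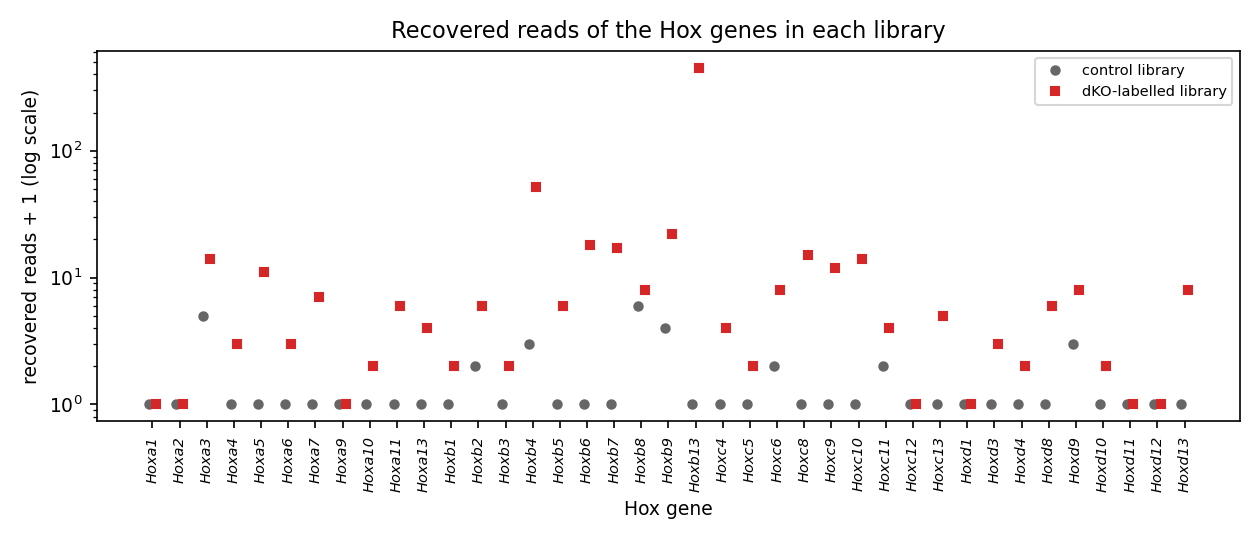
Recovered reads plus 1 (vertical, log scale) of each of 39 Hox genes (horizontal) in the control library (grey circles) and the dKO-labelled library (red squares), without error bars since each group has 1 library. Hoxb13 reached 451 reads in the dKO-labelled library against 0 in the control.

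Genes of lipid and xenobiotic metabolism were higher together in the dKO-labelled library. Of 18 measured cholesterol biosynthesis genes, 14 were at least 2-fold higher and 0 lower. Their median log2 ratio of 1.79, 1.28 above that of the measured genes, was reached by 0 of 10000 random lists matched on expression. Examples were Pmvk (7.75-fold), Lss (6.20-fold) and the sterol carrier Stard4 (5.34-fold, 3.54 to 8.36). Of 21 xenobiotic metabolism genes, 16 were at least 2-fold higher and 0 lower (median 1.74, percentile 100). Gstm1 was 14.2-fold, Akr1c19 11.5-fold and Ugt2b34 9.55-fold (7.11 to 13.1) higher. Reads of these genes can be shared with close paralogs, as for Gstm3 and Akr1c14, so their values are uncertain. List members from 1 family are not independent, which the random lists do not reflect. Of 15 fatty acid oxidation and ketogenesis genes, 10 were higher and 0 lower (median 1.27, percentile 100), among them Acaa2 (9.17-fold, 6.47 to 13.4), Ehhadh (4.72-fold) and Acadm (4.51-fold). Relative to the median of measured genes, 12, 13 and 5 members of these lists lay at least 2-fold above and 0, 0 and 2 at least 2-fold below.

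Interferon response and antimicrobial genes lay at the other end. Of 18 measured interferon response genes, 0 were at least 2-fold higher and 5 lower (median log2 ratio -0.50, percentile 0), including Oas2, Ifi44 (4.35-fold lower, 2.33 to 8.72), Usp18 (3.73-fold, 2.82 to 4.99) and Rsad2 (2.34-fold, 1.89 to 2.89). Of 10 antimicrobial genes of the epithelium, 4 were lower and 3 higher (median -0.52, percentile 0.11). Relative to the median of measured genes the counts were 5 lower and 0 higher, and for the interferon list 9 lower and 0 higher. Duox2, a hydrogen peroxide-producing oxidase, was 6.51-fold lower (5.02 to 8.55) and the C-type lectin gene Reg3b 5.29-fold (4.32 to 6.52), whereas Ang4 was 2.64-fold higher (2.08 to 3.37). Immediate early and stress genes had a median of -0.08 (percentile 1.98), with Socs3 2.12-fold lower and Hsph1 3.41-fold higher. It had 1 member in each direction, and relative to the measured genes 1 higher and 4 lower.

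**Figure D3:**
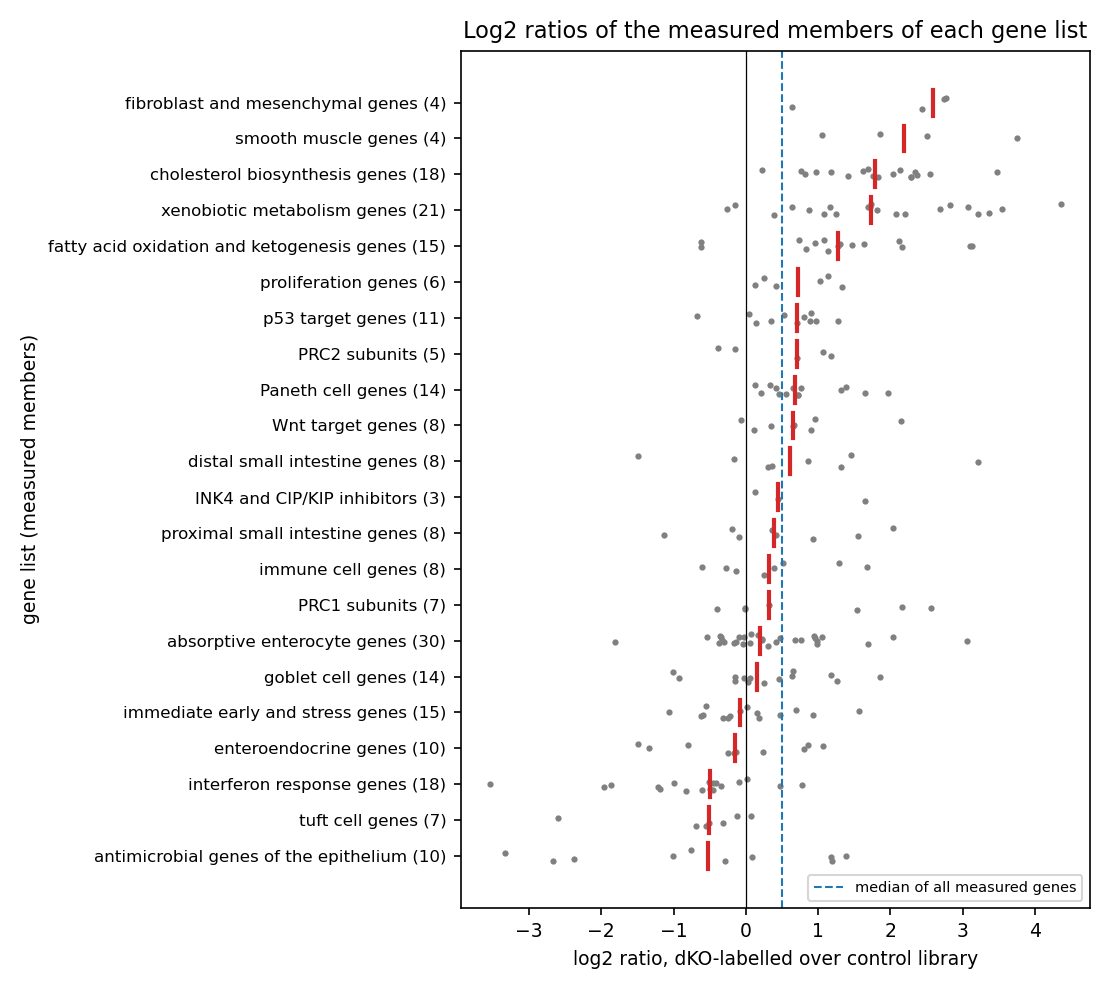
Log2 ratio of the dKO-labelled over the control library (horizontal) for each measured member (grey points, spread vertically at random) of each gene list with at least 3 measured members, the number in brackets, without the sex-linked genes. Red bars are list medians and the dashed line is the median of all measured genes at 0.51. Medians of the stromal, cholesterol and xenobiotic lists lie above the line, and interferon, tuft cell and antimicrobial medians lie below 0.

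Markers of the epithelial lineages were examined next. Absorptive enterocyte genes had a median log2 ratio of 0.19 over 30 genes (percentile 55.3), with 4 at least 2-fold higher, including the disaccharidases Sis (8.70-fold, 6.19 to 12.6) and Lct (4.15-fold, 3.53 to 4.89) and the glucose transporter Slc2a2 (3.49-fold), and Apob lower (relative to the measured genes, 3 higher and 2 lower). Goblet cell genes (14 genes, median 0.15, percentile 12.3) had 3 higher and 1 lower, with Tpsg1 and Spdef 4.38- and 2.35-fold higher and Fcgbp 2.01-fold lower (1.87 to 2.18). Relative to the median of measured genes, 1 goblet cell gene was at least 2-fold above and 2 at least 2-fold below. Paneth cell genes (14 genes, median 0.69, percentile 90.8) had 4 higher, among them Defa26, Ang4 and AY761184, of which the defensin genes share near-identical sequence. Relative to the measured genes 2 Paneth cell genes were higher. Tuft cell genes, markers of the chemosensory lineage, had a median of -0.51 over 7 genes (percentile 0.22), led by Trpm5 (6.35-fold lower, 4.37 to 9.50), but reached only percentile 15.4 among genes with a mean of at least 100. Of the tuft cell genes 1 was at least 2-fold lower, and 4 were relative to the measured genes. Enteroendocrine genes were mixed (10 genes, median -0.16, percentile 1.13). The hormones Pyy and Sst were 2.98- and 2.65-fold lower and the granin Chga was 2.10-fold higher. The percentile became 53 among genes with a mean of at least 100, where the median was 0.23. Relative to the measured genes 3 were lower and 0 higher, against 2 and 1.

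Along the length of the intestine, proximal genes had a median of 0.39 (8 genes, percentile 69.9) and distal genes 0.61 (8 genes, percentile 78.3, with 3 higher and 1 lower, or 1 and 1 relative to the measured genes), with the vitamin B12 receptor gene Cubn at 3 and 49 reads (14.7-fold, 4.75 to 73.8). Among crypt stem cell genes only Slc12a2 was measured (39 and 70 reads, and 107 and 231 over the whole list), among Wnt antagonists Kremen2 (12 and 30 reads, and 33 and 97 over the list). Wnt target genes had a median of 0.65 (8 genes, percentile 58.7), with the cyclin gene Ccnd2 4.48-fold higher (3.58 to 5.65), and proliferation genes 0.72 (6 genes, percentile 57.0), with Mki67 at 12 and 32 reads. At least 2-fold higher were 3 proliferation genes, and 0 relative to the measured genes.

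Within the INK4 and CIP/KIP family of cell cycle inhibitors (3 measured genes, median 0.44, percentile 41.8), Cdkn2b was 3.18-fold higher (2.49 to 4.08). The p53 target genes had a median of 0.71 (11 genes, percentile 87.2), with Bax 2.47-fold higher. Relative to the measured genes 0 p53 targets were at least 2-fold higher and 1 was lower. PRC1 subunit genes (7 genes, median 0.31, percentile 22.7) included Cbx6 (5.21-fold) and Bmi1 (3.03-fold, 1.97 to 4.79) higher, and PRC2 subunit genes had a median of 0.71 (5 genes, percentile 73.8), with 2 higher and 0 relative to the measured genes. Under the other settings the percentiles ranged from 23.0 to 85.1 for PRC1 and from 13.6 to 79.9 for PRC2.

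Markers of other cell types and of sex differed between the libraries, and they stand beside every group above. Fibroblast and mesenchymal genes had a median log2 ratio of 2.59 over 4 genes (percentile 99.95), with Col1a1 at 4 and 43 reads and Col3a1 at 8 and 72. Smooth muscle genes had a median of 2.18 over 4 genes (percentile 99.5), with Acta2 at 3 and 72 reads, and with 4 higher or, relative to the measured genes, 3. Immune cell genes had a median of 0.32 (8 genes, percentile 22.4), with 2 higher and 0 lower, or 1 and 1 relative to the measured genes. Few members of the remaining lists were measured: the endothelial gene Tie1 had 48 and 5 reads (66 and 55 over the whole list, in which Lyve1, Plvap and Vwf, named after their values were seen, had 1 and 19, 3 and 13, and 0 and 10), the enteric neuron gene Ret 33 and 17 (44 and 32 over the list), and the acinar genes Reg1 and Cela1 88 and 144 and 34 and 49. Erythroid genes had 1 read in the control and 0 in the dKO-labelled library. Xist, expressed from the inactive X chromosome, had 80 reads in the control and 1 in the dKO-labelled library, while Ddx3y had 0 and 131 and Eif2s3y 0 and 116, so that the sex of the animals and the genotype label cannot be separated. The list of sex-linked genes (3 measured) had a median of 5.77, at percentile 100. It joins Y-linked genes with Xist, so this median follows the make-up of the list and adds nothing to the single genes.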

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

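Each genotype had 1 library, so leaving out replicates was not possible. No paired analysis was possible because no result comes from a test on replicates. The planned rule on adjusted p-values was not run, since the table holds unadjusted ones, and the planned limit of at most 1 normalised read could not be met, because the lowest control value is above 1. It was replaced, after seeing the data, by 0 reads. Also chosen after seeing the data were the median set to 0, thinning (scaled by totals or by the median ratio over all rows, with the same values), random lists matched on transcript length, the added read taken off, the summed rows, the unadjusted and binomial p-values, and all settings for list percentiles other than unmatched lists, for medians relative to the measured genes and, except for the limit of 20, for near-silent genes.

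Genes higher and lower numbered 972 and 436 with total counts, 528 and 818 with the upper quartile, 664 and 652 with TMM, 680 and 642 with the median set to 0, and 898 and 419 after thinning. They numbered 3704 and 892 with no filter, 358 and 104 at a mean of at least 100, 627 and 104 with the counting interval beyond 2-fold, 104 and 19 with the authors' unadjusted p-values and 3013 and 698 with the binomial test, which compares the libraries alone. Pseudocount 5, the added read and summed rows kept both counts within 1.5 times. Total counts, the upper quartile and TMM shift every log2 ratio down by about 0.30, 0.64 and 0.52, so absolute directions near 0 follow the scaling. Rnf2 was at -0.32 with the upper quartile, -0.20 with TMM and -0.19 with the median set to 0, against 0.31, and Ring1 stayed within its counting interval.

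Near-silent Hox genes detected in the dKO-labelled library numbered 7, 1 when at least 20 reads were required and 12 at 5 reads against 0 reads. For the other developmental factors the number was 8, 5 with the upper quartile, 1 at 20 reads and 15 at 5. For all genes it was 259, 169 with the upper quartile, 62 at 20 reads and 421 at 5. In the other direction all genes gave 44, then 77 with the upper quartile, TMM, the median set to 0 and thinning, 10 at 20 reads and 89 at 5.

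Over 23 lists and 13 settings, 10 pairs had fewer than 3 measured genes and gave no value. Of the other 289 percentiles, 284 stayed on their side of the outer 2.5% tails. Enteroendocrine genes left them at a mean of at least 100 (percentile 53, with their median turning from -0.16 to 0.23) and after thinning under both scalings of the thinned reads (3.67), tuft cell genes at a mean of at least 100 (15.4), and enterocyte genes entered them with unmatched lists (2.35). Relative to the measured genes, list medians moved beyond counting error as follows. With no filter enterocyte genes were at -0.42, smooth muscle 1.12, distal -0.17 and sex-linked 3.44. At a mean of at least 100 enterocyte genes were at -0.14, Paneth 0.34, enteroendocrine -0.086, tuft -0.44, proximal 0.10, cholesterol 1.10 and interferon -0.81. After thinning proliferation genes were at 0.71 and antimicrobial genes at -1.24, and sex-linked genes were at 3.78 with pseudocount 5 and 6.28 without the added read. Fewer genes enter at the higher minimum; other causes were not tested. Percentiles between the tails still varied over the settings other than the main one, from 23.0 to 85.1 for PRC1 subunits, 13.6 to 79.9 for PRC2 subunits and 4.45 to 45.8 for immune cell genes. Of 725 values of 145 named genes under 5 settings, 182 left the counting interval of the main value. The scalings among these settings shift all genes alike, by at most 0.64 log2 units. Depth limits the low genes most: 28.7% of transcripts had no read in either library.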

Other observations

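All tests here were chosen after the results were seen. Genes of basic cell machinery, in groups also assembled after seeing the data, had medians above that of the measured genes. All 70 measured cytosolic ribosomal protein genes had log2 ratios above 0 with the deposited scaling, with a median of 0.81, 0.30 above the measured genes, and 0 of 10000 matched random lists reached it. Of these 70, 18 were at least 2-fold higher, while 26.2% of all measured genes were. Across genes, the log2 ratio was lower for longer transcripts (Spearman's rho -0.19, genes not being independent), and these transcripts are short, with a median of 843 bases against 2825. Against random lists matched on length as well, still 0 of 10000 reached the ribosomal median and 1 the respiratory one. Of 62 respiratory chain genes, 61 were above 0, 26 were at least 2-fold higher and 0 lower (median 0.84, 0.34 above the measured genes). Upper-quartile scaling lowers every ratio by about 0.64 and leaves the differences from the measured genes nearly as they are. The colon-associated genes Car4 (49 and 169 reads) and Slc26a3 (4 and 51) had more reads in the dKO-labelled library, whereas Car1 had 0 in both.

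Most genes beyond 2-fold were higher in the dKO-labelled library, 86.2% with the deposited scaling and 69.0% with total counts and no read removed. After thinning to equal reads, the same median rule gave a size factor ratio of 1, and 68.2% of such genes were higher. Thinning with that ratio amounts to total-count scaling, so it cannot test depth apart from the scaling. The share was 50.5% with TMM, 51.4% with the median set to 0 and 39.2% with the upper quartile, so the excess itself follows the scaling. Without the 10 most abundant transcripts of either library the ratio of total reads was 1.40, against 1.36 with them. A few abundant RNAs thus had little effect on total-count scaling. The deposited scaling follows a median over rows and not total reads, so this ratio cannot test their part in the 86.2%. The deposited size factors may carry the shift: their ratio of 1.11 equals the median ratio over all rows (1.11). Of these rows 28.7% are empty in both libraries, while transcripts detected in both give 1.54. Without added standards a general difference in RNA content, by genotype or by sex, stays open and untested.

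A set of 7 Hox genes and 8 other developmental factors, near-silent in the control, was detected in the dKO-labelled library, which is where loss of PRC1 would place them. Greater depth alone is argued against, since 6 Hox genes and 6 other factors met the rule after thinning to equal reads. They need not be the same genes, because after thinning a gene with 2 control reads, such as Hoxb4, also counts as near-silent. With the changed scaling the limit of 10 is also reached with fewer reads in the dKO-labelled library. The thinning was 1 random draw, and no share over all genes is given beside it. Stromal cells are argued against for Hoxb13, with 6.26 times the reads of the most abundant of 21 stromal markers (4.88 to 8.15). They may contribute to the other factors, since the stromal markers lay 1.56 log2 units above the measured genes. Of the 8 other factors, 1 is on a list of 33 mesenchymal and vascular factors. This count follows the limit of 10 normalised reads and does not show that stromal factors are absent. Just below the limit were Foxf1 (0 and 9 reads), Foxf2 (0 and 8) and Nkx2-3 (0 and 7). Prrx1 (9 and 4 reads) and Hlx (3 and 0) went the other way. Summed Hox reads without Hoxb13 were 11.6-fold higher (7.28 to 19.6), more than the summed stromal reads at 5.38-fold (4.34 to 6.73). Stroma in proportion to that sum would fall short of the Hox difference. Single stromal markers with control reads spread from 1.62-fold for Vim to 21.6-fold for Acta2, so a stromal share is not excluded. Colon cells cannot be told apart from a change in villus cells as a source of Hoxb13, since 3 of 5 colon markers in the table had at least 10 reads and the others at most 1, and a genotype or sex effect stays open.

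The densest transcripts differed less in reads between the libraries than the next densest: the median read ratio was 1.18 for 37 measured genes above 0.8 reads per base and 1.5 for those between 0.4 and 0.8. Prap1 had 989 and 975 reads, Zg16 961 and 957, Apoa1 1552 and 1560, and Apoa4 2529 and 2618, but Crip1 had 479 and 610 and Spink4 324 and 493. Of the 37 genes 2.70% were beyond 2-fold, against 14.4% of those between 0.4 and 0.8. The highest value among genes with a matched transcript length was 1.60 reads per base, below the limit of 2 that would hold if reads starting at the same base and strand were counted once, so removal of duplicate reads is a candidate explanation that could compress the ratios of abundant villus genes. Ratios of enterocyte genes may therefore be understated, and no biological explanation was tested.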
